A study of Mus musculus with 6 samples.

How the data were processed

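RNA of mouse CD8+ T cells was measured on 6 whole-transcript gene expression arrays (Affymetrix), 3 from cells labelled Dot1l knockout and 3 from cells labelled wild type. Per the labels' protocols, mice with a floxed Dot1l gene were crossed with mice carrying Cre recombinase under the Cd4 promoter, which is active in developing T cells, and CD8+ T cells were purified from lymph nodes and spleen with a magnetic isolation kit. Labelled cDNA was made from total RNA with a whole-transcript kit. Groups and replicate numbers were taken from the submitters' labels. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The labels name no array batch, and scan dates were not used here.

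The deposited table holds log2 expression values, which the authors obtained with RMA in R 3.1.1, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set by median polish. Its settings, the annotation version and the genome build are not given in the sources used here, nor is any centring or later filtering of the values. Array medians of the deposited log2 values lay between 3.69 and 3.78 and single values between 1.03 and 12.9. RMA compresses differences of weakly expressed genes, so a fold computed from these values can understate the change of a dim probe set. For arrays there is no count depth, and the number of arrays limits the precision. The median level of 1394 olfactory and vomeronasal receptor genes, which T cells are not known to use, was 2.28, and their 95th percentile of 3.83 served as a guide to background.

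The table held 41345 probe sets. In the platform annotation used here, 23521 named exactly 1 gene symbol, 1814 named several and 16010 were unnamed. Of the probe sets with 1 symbol, 23328 were found in the RefSeq gene table of the mouse by gene identifier, and 0 symbols changed. No coordinates are given, because the table names no build. Probe sets with several or no symbols were kept out of the gene tests and are described only in the closing section. Of the 1082 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays was used, which left 22180 genes.

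Each gene was tested for knockout-labelled minus wild type arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust fitting, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes. A gene passed at an adjusted p under 0.05. Values are log2 means ± SD of 3 arrays per group, differences are given with their standard error (SE), and folds are 2 raised to the size of the difference. The 24 gene lists, with 399 members of which 351 were measured, were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation between genes and fry, which tests whether the genes of a list move on balance one way, were run as alternatives. For each list, genes were also counted after adjustment over the list alone. List members that were unnamed or shared a probe set with another gene were not measured. The lists covered Dot1l complex partners, T cell receptor and co-receptor signalling, naive T cells and quiescence, memory CD8 T cells, cytotoxic effectors, NK receptors and adaptors, inhibitory receptors and exhaustion, STAT5 and common gamma chain cytokine signalling, Polycomb repressive complex 2, cell cycle, apoptosis and p53, methionine uptake and methyl donor metabolism, interferon-stimulated genes, glycolysis, immediate early and dissociation stress genes, and markers of B cells, plasma cells, monocytes with macrophages and neutrophils, dendritic cells, erythroid cells, platelets with megakaryocytes, CD4 helper with regulatory T cells, gamma delta with innate-like T cells, and stroma with endothelium.

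The tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says that a choice was made later. Named genes were Dot1l, Stat5a and Stat5b, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, and the 4 members with the smallest p in each list, whether or not they passed. Predicted genes, small RNAs, receptor gene segments, immunoglobulin genes and olfactory or vomeronasal receptors were counted but not named among the largest changes. Other genes named are said to have been chosen after their values were seen. The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization and median centring over all probe sets, level filters at the 25th and 50th percentile, trend with robust fitting, array weights, the mean of a gene's probe sets, all probe sets, and other thresholds. A covariate was added after the data were seen.

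The procedure was tested on simulated data for the 22180 genes of this comparison, with 100 genes changed at each of 2 sizes. It recovered 85% of the genes changed by 1 on the log2 scale and 99% of those changed by 2, with 7 false calls. With no change simulated it called 0 genes and 0 lists. Genes were simulated independently with normal noise, without correlation between genes or effects shared by an array. The 0 lists therefore do not show how the list test treats correlated genes. When the cell cycle list alone was shifted by 0.5 in such data, camera gave it an adjusted p of 3.6e-34. Camera with an estimated correlation gave it 0.0037, a far larger value although the genes were simulated without correlation. Figures were drawn with matplotlib 3.10.9.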

Results

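Gene expression was measured in CD8+ T cells of C57BL/6 mice on 6 arrays, 3 labelled wild type and 3 labelled Dot1l knockout. The comparison asks which transcripts differ when T cells lack Dot1l, the methyltransferase that modifies lysine 79 of histone H3. Arrays of a group correlated at r of 0.994 to 0.995 over genes within the knockout-labelled group, 0.989 to 0.993 within the wild type group and 0.984 to 0.987 between the groups. The leading principal component held 49.2% of the variance and separated the groups, with scores of -22.9 to -22.0 in wild type arrays and 20.9 to 24.3 in knockout-labelled arrays. No array repeated another.

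Dot1l itself was not lower in the knockout-labelled arrays. Its probe set read 7.30 ± 0.04 in knockout-labelled and 7.20 ± 0.25 in wild type arrays (n = 3 each, as for all values that follow), a difference of 0.10 on the log2 scale (SE 0.13, 95% interval -0.20 to 0.40, limma with Benjamini-Hochberg adjusted p = 0.765). The 3 wild type values were 7.46, 6.96 and 7.18, and the 3 knockout-labelled values were 7.31, 7.26 and 7.33. Without wild type replicate 2 the difference was -0.02. The exon removed by the floxed allele is not given in the sources used here, and probes outside a deleted exon do not check the labels, so directions below refer to arrays as labelled. Stat5b, a transcription factor activated by interleukin receptors, fell from 8.10 ± 0.09 to 7.43 ± 0.09 (log2 difference -0.67, SE 0.10, adjusted p = 0.00572). Its paralogue Stat5a read 7.29 ± 0.07 against 7.66 ± 0.20 (-0.37, SE 0.12, adjusted p = 0.139), which did not pass.

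The largest rises in knockout-labelled arrays included receptors, a death ligand and an antiviral protein. Nrp1, a co-receptor for semaphorins and growth factors, rose 13.9-fold, from 4.19 ± 0.14 to 7.98 ± 0.04 (log2 difference 3.80, SE 0.11, adjusted p = 3.6e-07). Ifitm3, an antiviral membrane protein induced by interferon, rose 8.39-fold (log2 3.07, SE 0.17), and Il12rb2, a chain of the interleukin-12 receptor, rose 6.99-fold (2.81, SE 0.14). Fasl, the ligand of the death receptor Fas, rose 6.23-fold from 6.36 ± 0.15 in wild type arrays (2.64, SE 0.11, adjusted p = 1.1e-05). Also among the 10 largest rises by the naming rule were Ogfrl1 (2.76, SE 0.27), Emp1 (2.67, SE 0.13), Gca (2.54, SE 0.16), the sialyltransferase gene St8sia6 (2.53, SE 0.13), Ctla2b (2.52, SE 0.12) and the chemokine receptor gene Ccr2 (2.52, SE 0.15). Adjusted p for these 10 lay between 3.6e-07 and 0.000399. The rise of Emp1 was 1.36 when its bright probe set was averaged with a dim one. Gca read 3.12 in wild type arrays, below the background guide of 3.83, so the size of its rise and its rank are uncertain.

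The largest fall was read by a probe set of Kcnma1, the pore-forming subunit of a calcium-activated potassium channel, from 10.3 ± 0.12 to 4.01 ± 0.23 (log2 -6.25, SE 0.13, a 76.3-fold difference, adjusted p = 5.68e-08). The probe sets of this gene disagreed. The other Kcnma1 probe set read 2.66 ± 0.02 in knockout-labelled and 2.77 ± 0.12 in wild type arrays (-0.11, adjusted p = 0.64 over all probe sets), below the background guide of 3.83, and the mean of both gave -3.18 (adjusted p = 1.09e-06). Dapl1, a gene of naive T cells, fell 5.24-fold from 9.85 ± 0.09 to 7.46 ± 0.30 (-2.39, SE 0.15, adjusted p = 4e-05), and Igfbp4, an insulin-like growth factor binding protein, fell 4.29-fold (-2.10, SE 0.14). Bpifa2 (-2.29, SE 0.21), the inhibitory NK receptor gene Klra6 (-2.06, SE 0.33), Slc35g1 (-1.56, SE 0.22), the interleukin-6 receptor gene Il6ra (-1.34, SE 0.10), Fam71b (-1.32, SE 0.16), Gimap7 (-1.30, SE 0.13) and Cyth3 (-1.30, SE 0.10) completed the 10 largest falls by the naming rule, with adjusted p up to 0.00652. That rule leaves out immunoglobulin genes, some of which fell further than Dapl1 and are given in the closing part. In knockout-labelled arrays Klra6 (3.29) and Fam71b (3.42) lay below the background guide, so the sizes and ranks of their falls are uncertain. All 20 genes named for the largest changes passed in each of the 6 fits that left out 1 array.

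**Figure D1:**
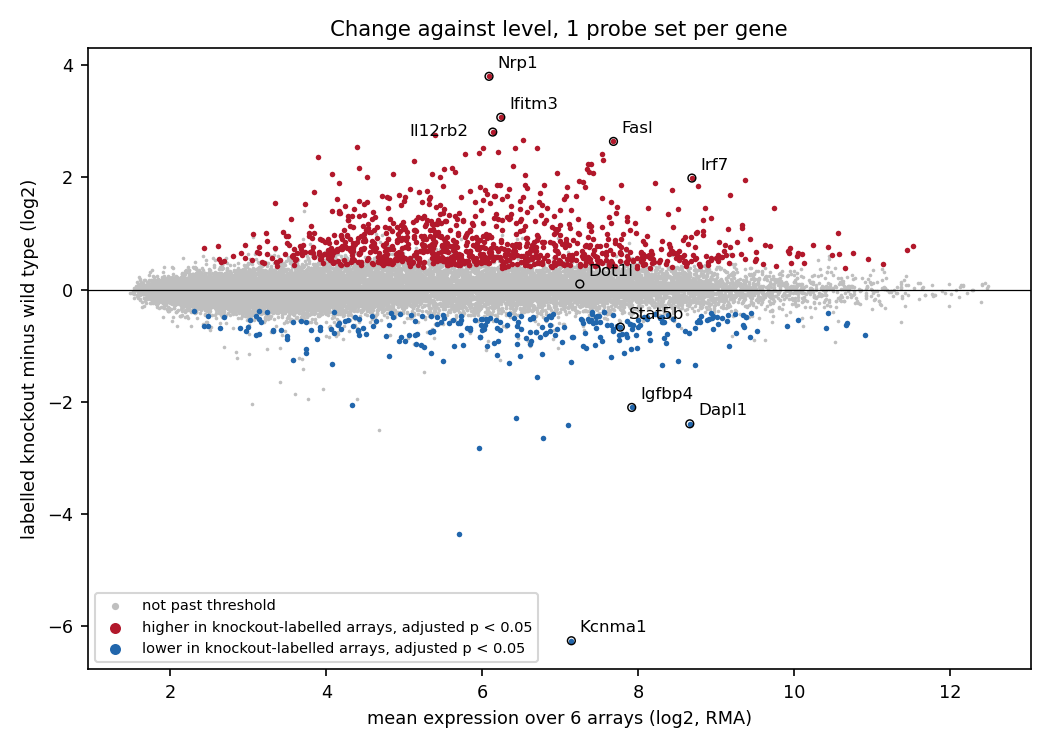
Log2 difference between knockout-labelled and wild type arrays (vertical axis) against the mean log2 expression over 6 arrays (horizontal axis), 1 point per gene. Red and blue points passed an adjusted p of 0.05 as higher or lower in knockout-labelled arrays; Kcnma1 lies at -6.25, Nrp1 at 3.80 and Dot1l near 0.

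Over all 22180 genes, 1220 passed (limma with Benjamini-Hochberg), 954 higher and 266 lower in knockout-labelled arrays. Changes of at least 2-fold were seen for 255 of the higher and 34 of the lower genes. In 5212 genes (23.5%) the groups did not overlap, against 10% by chance for 3 against 3 arrays, and these included all 1220. The surplus of rises moved with scaling: 78.2% of the calls were higher with the deposited values, 68.8% after median centring (755 higher, 342 lower) and 57.1% after another quantile normalization (625 higher, 470 lower). Both rescalings ran over all probe sets, unnamed ones included, and moved the tested genes down. The median difference of the tested genes was -0.012 as deposited, -0.062 after median centring and -0.058 after quantile normalization. The count fell to 745, 696 and 615 without knockout replicate 1, 2 or 3 and to 780 without wild type replicate 3, and 536 genes passed in all 6 such fits. A block of 5333 unnamed probe sets outside the tests read higher in the same arrays, at a median log2 difference of 0.43, and 5 genes passed once that shift entered the fit as a covariate, a choice made after seeing the data. The median size of the log2 differences of the 1220 genes was 0.715 without and 0.717 with the covariate, while their standard errors grew. Added noise also enlarges such sizes, so their likeness does not show that the differences stayed the same.

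Most interferon-stimulated genes rose in knockout-labelled arrays, and their list passed as higher, a call that did not hold with an estimated correlation. Of 21 measured members 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 difference of 1.57. Irf7, a transcription factor that amplifies type I interferon production, rose from 7.69 ± 0.09 to 9.68 ± 0.18 (1.99, SE 0.12, adjusted p = 3.74e-05). Oasl2, an antiviral synthetase-like protein, rose 5.33-fold (2.41, SE 0.15), the RNA sensor gene Ifih1 3.73-fold (1.90, SE 0.15) and Ifit1 4.71-fold (2.24, SE 0.18). Camera gave an adjusted p of 3.28e-28 for the list and an adjusted p of 0.127 with an estimated correlation. The estimated form also gave the larger p for a simulated list of uncorrelated genes. Its loss of a call, here and below, thus does not by itself show correlation as the cause. In the same arrays 4 of 13 B cell markers rose, among them Cd22 (1.29), and Ighm fell (-0.60), 3 of 12 dendritic cell markers rose, among them Itgax (1.14), in a list that did not pass (adjusted p = 0.26), and 4 of 20 immediate early genes rose, among them Fosb (1.22).

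The memory and cytotoxic CD8 T cell lists passed as higher in knockout-labelled arrays and the naive list as lower. With an estimated correlation none of these calls held (adjusted p = 0.127, 0.150 and 0.127 in that order). In the memory list 13 of 19 measured genes rose and 1 fell (15 and 1 adjusted over the list alone), with a median difference of 0.77. Eomes, a T-box factor of memory cells, rose from 8.29 ± 0.04 to 9.56 ± 0.05 (1.27, SE 0.10, adjusted p = 9.86e-05). Ccr2 is given above, the integrin gene Itgb1 rose by 1.45 (SE 0.11) and the chemokine gene Xcl1 by 1.77 (SE 0.16). The member that fell was Cxcr5 (-0.98, SE 0.10), named after its value was seen. In the cytotoxic effector list 11 of 20 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.62. Beside Fasl, the granzyme gene Gzma rose 4.24-fold from 5.91 ± 0.22 to 7.99 ± 0.20 (adjusted p = 7.24e-05), the chemokine gene Ccl4 by 1.61 (SE 0.15) and the calcium-binding protein gene S100a6 by 1.87 (SE 0.19).

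In the naive and quiescence list 0 of 18 genes rose, 5 fell and 13 did not pass, also when adjusted over the list alone, with a median of -0.10 and a mean of -0.39. The falls were Dapl1, Igfbp4, Il6ra, the actin cross-linker gene Actn1 (-0.68, SE 0.10, adjusted p = 0.00388) and Lef1 (-0.63, SE 0.10), the last named after its value was seen. Camera adjusted p was 1.04e-14 for the memory list, 8.32e-15 for the cytotoxic list and 0.00183 for the naive list. With an estimated correlation the adjusted p was 0.127, 0.150 and 0.127 in that order. Of the B cell markers 4 of 13 rose in the same arrays and Ighm fell (-0.60), of the dendritic cell markers 3 of 12 rose in a list that did not pass (median -0.04, adjusted p = 0.26), and of the immediate early genes 4 of 20 rose.

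**Figure D2:**
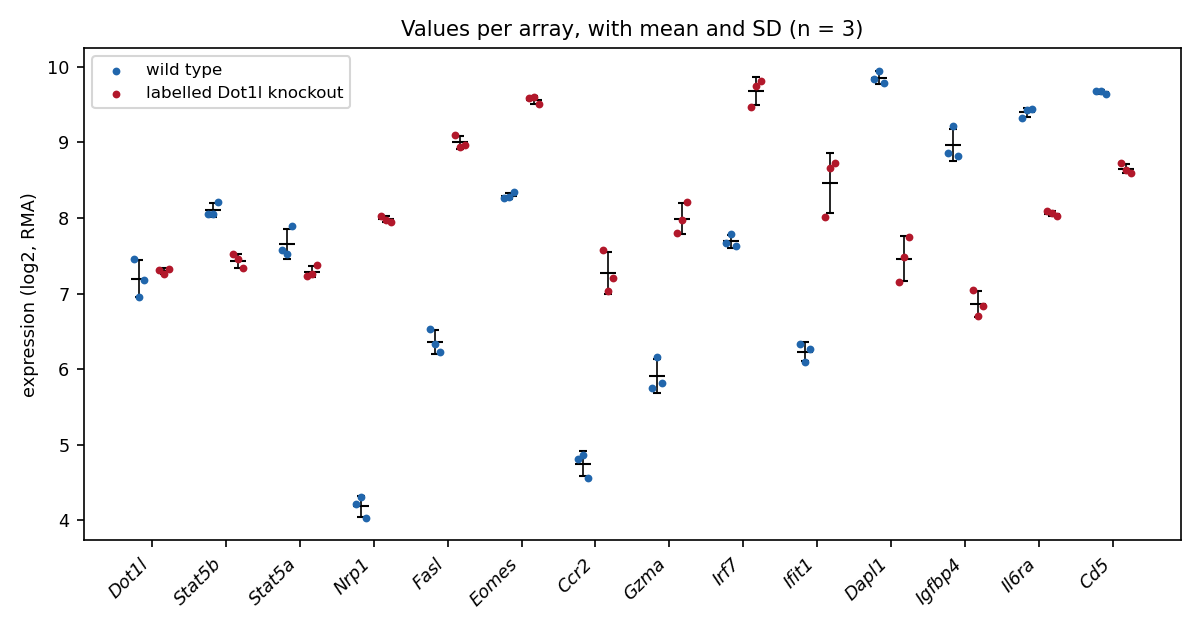
Log2 expression of 14 genes in each array, blue for wild type and red for arrays labelled Dot1l knockout, with black bars for the mean and SD of 3 arrays. Dot1l overlapped between the groups (7.20 ± 0.25 and 7.30 ± 0.04), while the groups lay apart for the other 13 genes, among them Nrp1 and Dapl1.

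NK receptor genes went both ways. Of 16 measured members 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.26. Klrc1, which encodes an NKG2 lectin, rose from 7.21 ± 0.13 to 8.51 ± 0.30 (1.30, SE 0.15, adjusted p = 0.00132). Cd160 rose by 0.98 (SE 0.16) and Klrc2 by 1.55 (SE 0.31), and Klra6 fell as given above. Camera adjusted p was 0.00913 for the list, 0.413 with an estimated correlation, 0.0727 without knockout replicate 1 and 0.252 among genes above the median level. The separate test with fry gave an adjusted p of 0.0786. Klrc2, which read 2.57 and so below the background guide in wild type arrays, did not pass without wild type replicate 3 or knockout replicate 1 or 3 (adjusted p = 0.0742, 0.0792 and 0.058). The same arrays held 4 higher and 1 lower of 13 B cell markers, 3 higher of 12 dendritic cell markers and 4 higher of 20 immediate early genes.

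Inhibitory receptor genes did not move as a list, with 3 of 16 higher and 2 lower (4 and 5 adjusted over the list alone), a median of -0.12 and a camera adjusted p of 0.654 (0.749 with an estimated correlation). Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, rose from 9.30 ± 0.07 to 10.07 ± 0.03 (0.77, SE 0.10, adjusted p = 0.00185), and its relative Nr4a3 by 0.93 (SE 0.17). Tigit rose by 0.52 (SE 0.10), and the checkpoint genes Lag3 (-0.56, SE 0.11) and Btla (-0.85, SE 0.17, named after its value was seen) fell. Nr4a3 did not pass without knockout replicate 2 or 3 (adjusted p = 0.0613 for both), Tigit without knockout replicate 1, 2 or 3 (0.0843, 0.0834 and 0.0522) and Lag3 without wild type replicate 1 or 3 or knockout replicate 2 or 3 (0.051, 0.0619, 0.0802 and 0.0608).

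In the list of STAT5 and common gamma chain signalling 6 of 20 genes rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 0.28. Pim1, a survival kinase, rose from 9.23 ± 0.14 to 10.02 ± 0.12 (0.79, SE 0.12, adjusted p = 0.00408), and the feedback inhibitor gene Socs3 rose by 0.57 (SE 0.10). The gene that fell was Stat5b. A probe set of Socs2, another feedback inhibitor, rose by 2.36 (SE 0.32, adjusted p = 0.00293), from 2.71 ± 0.38 to 5.07 ± 0.73, whereas the other Socs2 probe set read 3.86 ± 0.19 against 3.84 ± 0.24 (0.02, adjusted p = 0.969 over all probe sets). Averaging probe sets gave 1.19 for Socs2 (adjusted p = 0.00843) and 0.50 for Pim1 (0.0199). The used Socs2 probe set was below the background guide in wild type arrays. Camera adjusted p for the list was 0.000196, and 0.278 with an estimated correlation. Beside these genes 4 of 13 B cell markers rose and 1 fell, 3 of 12 dendritic cell markers rose and 4 of 20 immediate early genes rose.

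Of 26 measured cell cycle genes 4 rose, 0 fell and 22 did not pass (7 and 0 adjusted over the list alone), with a median of 0.27 (0.14 after another quantile normalization) and a camera adjusted p of 1.13e-06 (0.104 with an estimated correlation). The cyclin gene Ccna2 rose by 0.88 (SE 0.15), the ribonucleotide reductase gene Rrm2 by 0.72 (SE 0.11), the topoisomerase gene Top2a by 0.56 (SE 0.11) and the replication helicase gene Mcm6 by 0.42 (SE 0.10, adjusted p = 0.0491). Mcm6 passed without wild type replicate 2 but not when any other array was left out (adjusted p = 0.11 and 0.137 without wild type replicate 1 and 3, and 0.0885, 0.159 and 0.192 without knockout replicate 1, 2 and 3), and it did not pass after either rescaling (0.0908 and 0.09). Top2a did not pass without knockout replicate 2 or 3 (0.0648 and 0.0809), nor Rrm2 with the mean of its probe sets (0.41, 0.0818). These arrays also had 4 of 13 B cell markers higher and 1 lower, 3 of 12 dendritic cell markers higher and 4 of 20 immediate early genes higher.

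Among glycolysis genes 2 of 14 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.18 (0.10 after another quantile normalization). Hexokinase gene Hk2 rose by 0.57 (SE 0.11, adjusted p = 0.0157) and lactate dehydrogenase gene Ldha by 0.46 (SE 0.10, adjusted p = 0.0295), while Pfkl differed by 0.45 (adjusted p = 0.0523) and Pfkp by 0.32 (adjusted p = 0.134). With trend and robust fitting Pfkl (0.0422) and Pfkp (0.036) passed, and Pfkl also with the 25th and 50th percentile filters (0.0432 and 0.0263). Camera adjusted p was 0.0275 for the list and 0.413 with an estimated correlation, and the call ended without knockout replicate 1 (0.0727), without wild type replicate 1 (0.0597) and after another quantile normalization (0.0682). It also ended with the mean of probe sets (0.0756), all probe sets (0.0654) and filters at the 25th or 50th percentile of level (0.0825 and 0.235). Hk2 did not pass without knockout replicate 1 or 3 (0.0611 and 0.0824) or after that normalization (0.133). Ldha passed without wild type replicate 2 and not without wild type replicate 1 or 3 or knockout replicate 1, 2 or 3 (0.0784, 0.0751, 0.0965, 0.11 and 0.116), nor after either rescaling (0.0576 and 0.124). With these genes 4 of 13 B cell markers rose and 1 fell, 3 of 12 dendritic cell markers rose and 4 of 20 immediate early genes rose.

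Apoptosis and p53 genes did not pass as a list, with 3 of 22 higher and 0 lower (the same numbers adjusted over the list alone), a median of 0.05 (0.01 after another quantile normalization and -1.2e-05 after median centring) and a camera adjusted p of 0.0767. That p was 0.279 with an estimated correlation, and it passed without wild type replicate 1 (0.0488) and with trend and robust fitting (0.0433). The separate test with fry also passed the list (adjusted p = 0.0139). Bcl2l11, which encodes the death-promoting protein Bim, rose from 7.88 ± 0.12 to 8.74 ± 0.07 (0.86, SE 0.11, adjusted p = 0.00158). Trp53inp1 rose by 0.52 (SE 0.09) and the cell cycle inhibitor gene Cdkn1a by 0.69 (SE 0.14), and Bcl2 differed by 0.34 (adjusted p = 0.141, or 0.0318 with trend and robust fitting). Trp53inp1 did not pass without knockout replicate 2 or 3 (0.0643 and 0.0604), nor Cdkn1a without wild type replicate 1 or knockout replicate 1, 2 or 3 (0.0576, 0.0973, 0.0746 and 0.0831).

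Of 20 immediate early genes, which respond to stimulation and to tissue dissociation, 4 rose, 0 fell and 16 did not pass (5 and 0 adjusted over the list alone). The median was 0.16 and camera gave an adjusted p of 0.000281, or 0.385 with an estimated correlation. Fosb rose 2.34-fold from 7.25 ± 0.15 to 8.47 ± 0.21 (1.22, SE 0.13, adjusted p = 0.000838), Egr1 2.18-fold (1.12, SE 0.14), Fos by 0.63 (SE 0.10) and Zfp36 by 0.51 (SE 0.10). Zfp36 did not pass without wild type replicate 3 or knockout replicate 1, 2 or 3 (0.0682, 0.0794, 0.0621 and 0.0705). Among B cell markers 4 of 13 were higher and 1 lower in the same arrays, and among dendritic cell markers 3 of 12 were higher.

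In the list of T cell receptor and co-receptor signalling 0 of 17 genes rose and 2 fell, also when adjusted over the list alone. Cd5, a surface protein that dampens antigen receptor signals, fell 2.01-fold from 9.66 ± 0.02 to 8.65 ± 0.06 (-1.01, SE 0.10, adjusted p = 0.000376), and the related Cd6 fell from 9.04 ± 0.09 to 8.27 ± 0.03 (-0.77, SE 0.10, adjusted p = 0.00201). Fyn differed by 0.31 (adjusted p = 0.138, or 0.0363 with trend and robust fitting) and Cd2 by 0.24 (0.318). The list median was 0.01 (-0.03 and -0.04 after quantile normalization and median centring) and the mean -0.08. Camera, pointing down, gave an adjusted p of 0.435 (0.506 with an estimated correlation), while fry gave 0.0139.

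Lists of chromatin complexes and methyl donor supply did not pass. Of 11 genes of Polycomb repressive complex 2, 1 rose and 0 fell (1 and 2 adjusted over the list alone), with a median of -0.06 and a camera adjusted p of 0.643 (0.716 with an estimated correlation). Phf19, an accessory subunit, rose by 0.53 (SE 0.10, adjusted p = 0.015), and Jarid2 (-0.42, adjusted p = 0.0725) and the methyltransferase genes Ezh1 (-0.33, 0.12) and Ezh2 (-0.33, 0.212) did not pass. Jarid2 passed with trend and robust fitting (0.0271), the 50th percentile filter (0.0367) and median centring (0.0419), and Ezh1 with trend and robust fitting (0.0364). Phf19 did not pass without wild type replicate 3 or knockout replicate 1 or 3 (0.0599, 0.0684 and 0.0586) or after another quantile normalization (0.0996). Of 8 Dot1l partner genes 0 passed by either adjustment and 1 had an unadjusted p under 0.05, with a median of 0.04 (-0.0059 and -0.0054 after quantile normalization and median centring) and camera adjusted p of 0.654 (0.749 with an estimated correlation). Mllt1 differed by 0.23 (adjusted p = 0.266), Kmt2a by 0.22 (0.514), Mllt10 by -0.14 (0.62) and Mllt3 by 0.08 (0.755). Of 13 genes of methionine uptake and methyl donors 0 passed by either adjustment and 1 had an unadjusted p under 0.05, with a median of -0.03 (-0.18 and -0.08 after quantile normalization and median centring) and camera adjusted p of 0.324 (0.444 with an estimated correlation). The methionine carrier gene Slc43a2 differed by -0.43 (0.106), Srm by -0.28 (0.285), Shmt2 by -0.19 (0.368) and Mtap by -0.20 (0.412).

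Markers of B cells were in part higher in knockout-labelled arrays. Of 13 measured, 4 rose and 1 fell, also when adjusted over the list alone, with a median of 0.24 (0.12 after another quantile normalization). Cd22, an inhibitory receptor of B cells, rose from 4.53 ± 0.30 to 5.82 ± 0.13 (1.29, SE 0.16, adjusted p = 0.00143), Ms4a1, which encodes CD20, from 3.24 ± 0.10 to 4.37 ± 0.26 (1.13, SE 0.14), and Fcmr by 0.82 (SE 0.16). Cd79a, named after its value was seen, rose by 0.86 (SE 0.21). Ighm, the heavy chain of IgM, fell from 10.98 ± 0.11 to 10.38 ± 0.06 (-0.60, SE 0.10, adjusted p = 0.00892). Camera adjusted p was 0.0177, but 0.385 with an estimated correlation, 0.0839 without wild type replicate 2, 0.0654 with all probe sets and 0.061 and 0.228 with filters at the 25th and 50th percentile of level. Ighm did not pass with the mean of its probe sets (-1.06, adjusted p = 0.18). Fcmr did not pass without knockout replicate 1 or 3 (0.0774 and 0.0934) or after another quantile normalization (0.063).

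Of 12 dendritic cell markers 3 rose and 0 fell (4 and 0 adjusted over the list alone). Members counted as markers by the list fixed beforehand, and the specificity of Bst1 for dendritic cells was not tested. The integrin gene Itgax rose from 4.38 ± 0.23 to 5.52 ± 0.26 (1.14, SE 0.16, adjusted p = 0.00324), the class II gene H2-Aa by 1.21 (SE 0.21) and Bst1 by 0.74 (SE 0.17), while H2-Ab1 differed by 1.09 (SE 0.31, adjusted p = 0.0875, or 0.00439 without wild type replicate 3). The median was -0.04 and the mean 0.28, and camera, pointing up, gave an adjusted p of 0.26 (0.413 with an estimated correlation, and 0.0483 without wild type replicate 3). H2-Aa did not pass without knockout replicate 1 or 3 (0.0515 and 0.0533), nor Bst1 without wild type replicate 1 or knockout replicate 1, 2 or 3 (0.0563, 0.0965, 0.121 and 0.12) or after another quantile normalization (0.0726).

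Other blood cell markers moved in single genes. Of 18 monocyte, macrophage and neutrophil markers 1 rose by either adjustment and 0 fell, with a median of -0.05 and a camera adjusted p of 0.952 (also 0.952 with an estimated correlation). The integrin gene Itgam rose by 0.60 (SE 0.12, adjusted p = 0.0214), but did not pass without wild type replicate 1 or 3 or knockout replicate 1 or 2 (0.0637, 0.0816, 0.0906 and 0.0732) or after another quantile normalization (0.127). Ms4a6c differed by 0.67 (0.0958), Adgre1 by -0.60 (0.115, or 0.0317 without wild type replicate 3) and Fcgr3 by 0.29 (0.184). Of 8 platelet and megakaryocyte markers the integrin gene Itgb3 alone rose, from 5.70 ± 0.22 to 7.28 ± 0.18 (1.58, SE 0.14, adjusted p = 0.000279), 0 fell, and the counts adjusted over the list alone were the same. Treml1 differed by -0.22 (0.342), Pf4 by 0.20 (0.463) and Gp9 by -0.23 (0.557). This list had a median of -0.07, a mean of 0.15 and a camera adjusted p of 0.654, pointing up (0.746 with an estimated correlation). For the same list fry gave an adjusted p of 0.0140. Of 5 plasma cell markers 0 passed by either adjustment and 1 had an unadjusted p under 0.05 (median -0.02, camera adjusted p 0.654, 0.741 with an estimated correlation), with Jchain at -0.86 (0.2), Tnfrsf17 at 0.07 (0.885), Derl3 at -0.04 (0.948) and Mzb1 at 0.02 (0.963). Of 5 erythroid markers 0 passed by either adjustment and 1 had an unadjusted p under 0.05 (median -0.14, camera adjusted p 0.435, 0.506 with an estimated correlation), with Car1 at -0.62 (0.115, or 0.0245 without knockout replicate 3), Slc4a1 at -0.38 (0.443), Klf1 at -0.14 (0.568) and Epb42 at 0.16 (0.64).

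Markers of other T cell subsets went both ways. Of 10 markers of CD4 helper and regulatory T cells 3 rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.12, a camera adjusted p of 0.938 and an adjusted p of 0.951 with an estimated correlation. Ikzf2, which encodes the transcription factor Helios, rose from 6.79 ± 0.13 to 7.95 ± 0.14 (1.16, SE 0.12, adjusted p = 0.000473) and Tnfrsf18, a costimulatory receptor, by 0.69 (SE 0.10), while Cd40lg fell by 0.88 (SE 0.15) and Izumo1r by 0.96 (SE 0.19). Izumo1r did not pass without knockout replicate 1 or 3 (0.0601 and 0.0602). Of 9 gamma delta and innate-like T cell markers 1 rose and 1 fell, also when adjusted over the list alone (median 0.01, or -0.16 and -0.04 after quantile normalization and median centring, mean -0.04, camera pointing down with an adjusted p of 0.886, or 0.892 with an estimated correlation). The transcription factor gene Maf rose by 0.69 (SE 0.10, adjusted p = 0.00313) and Cd163l1 fell by 0.79 (SE 0.16, adjusted p = 0.0226), which did not pass without wild type replicate 1 or 3 or knockout replicate 2 or 3 (0.0685, 0.0706, 0.0863 and 0.102). Maf did not pass with the mean of its probe sets (0.40, 0.0759). Il23r differed by -0.34 (0.203) and 5830411N06Rik by 0.24 (0.434). Of 10 stromal and endothelial markers 0 passed and 1 had an unadjusted p under 0.05 (0 and 1 adjusted over the list alone, median -0.02, camera adjusted p 0.618, 0.741 with an estimated correlation), with Sparc at -0.49 (0.0543, or 0.0452 with array weights and 0.0451 with the 25th percentile filter), Pecam1 at -0.21 (0.295), Vcam1 at 0.18 (0.681) and Col1a2 at 0.12 (0.687).

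Camera passed 10 of the 24 lists at its preset correlation, 9 higher and 1 lower, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. As the simulation showed, the estimated form gives larger p-values even without correlation between genes. Fry passed 12 lists. Medians of lists that did not pass also moved with scaling. Quantile normalization gave -0.26 for the CD4 list, -0.12 for the monocyte, macrophage and neutrophil list, -0.08 for the stromal list and -0.06 for the plasma cell list, and median centring gave -0.11 for the Polycomb list, -0.09 for the dendritic cell list and -0.12 for the platelet list.

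**Figure D3:**
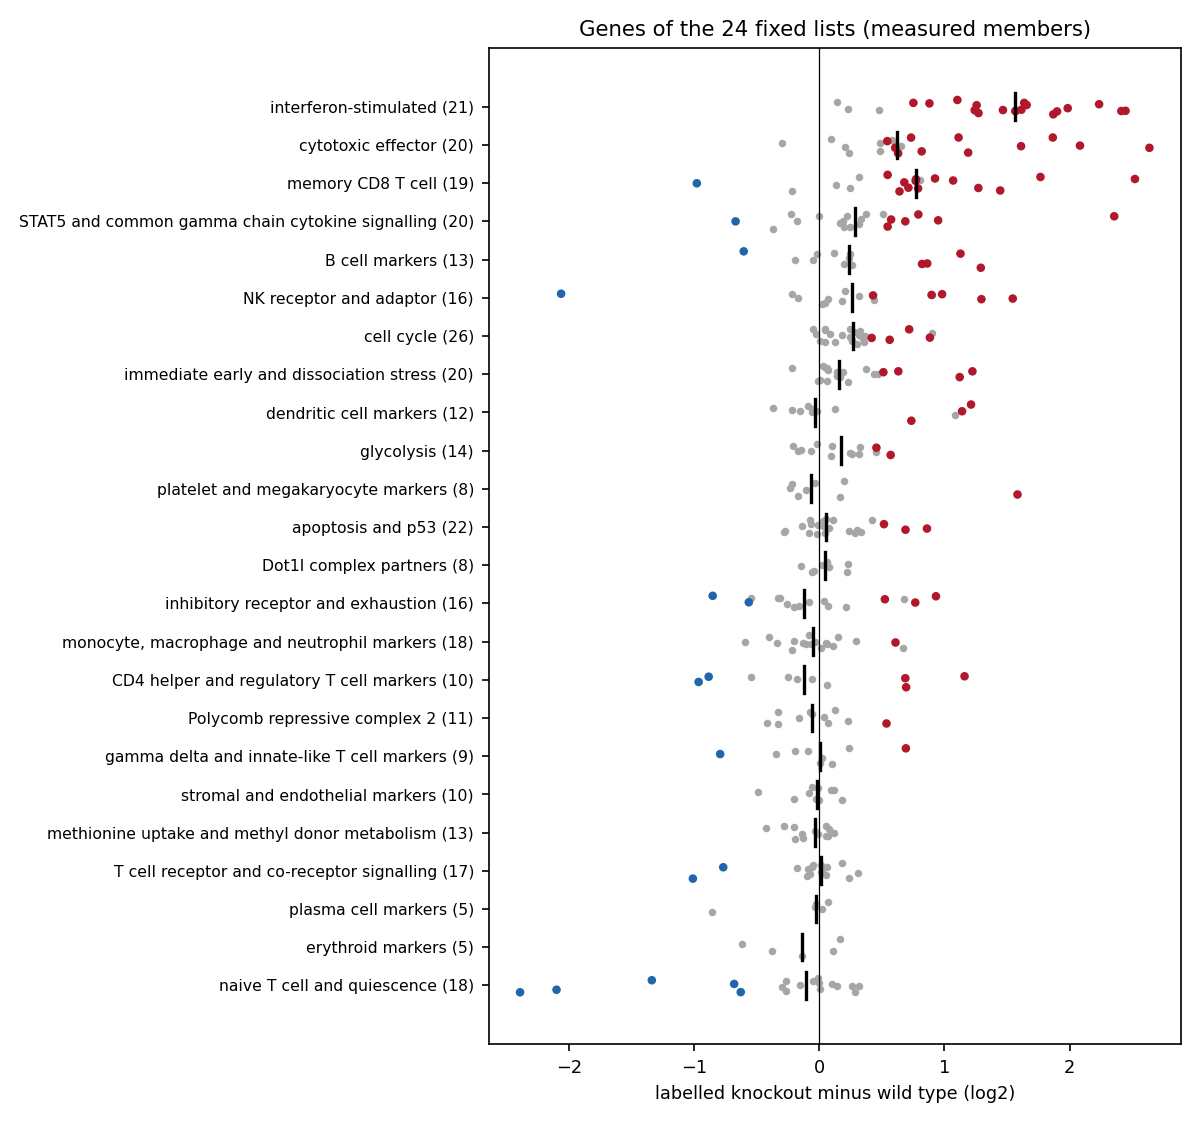
Log2 difference between knockout-labelled and wild type arrays for the measured members of the 24 lists, 1 point per gene, ordered by the list mean, with black bars at list medians and list sizes in brackets. Red and blue points passed an adjusted p of 0.05 over all genes as higher or lower; 18 of 21 interferon-stimulated genes are red and 5 of 18 naive genes are blue.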

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

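The tests of background, scaling, blood cell markers and Kcnma1 in this part were chosen after the results were seen, and the test on microRNA genes was chosen before its result was seen.

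Probe sets outside the gene tests held signal that differed between the groups. The 5333 unnamed probe sets with identifiers below the first named one had a median log2 difference of 0.431 (SE of the median 0.00969, knockout-labelled minus wild type), with 537 higher and 5 lower past an adjusted p of 0.05 (limma over all probe sets). The SE of a median in this part is taken over probe sets or genes as if independent. It does not measure the spread between arrays. Their medians per array were 3.80, 3.50 and 3.70 in wild type and 4.12, 4.34 and 4.29 in knockout-labelled arrays (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Among 1814 probe sets with several gene symbols, 40 were higher and 10 lower. Among the 10677 other unnamed probe sets, 207 were higher and 103 lower.

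A candidate explanation for the shift of the low-identifier probe sets is genomic DNA or a higher background. Olfactory and vomeronasal receptor genes did not rise, with a median difference of -0.054. They cannot decide the question, because RMA corrects the background and compresses differences of weakly expressed genes. Their median level was 2.28, against 3.95 for the low-identifier probe sets. An array-wide offset was not seen in the other unnamed probe sets, whose median difference was -0.0199. Those sets were dim, at 3.24 in knockout-labelled and 3.29 in wild type arrays, so an offset in brighter signal stays open. The upper quartile over all probe sets was 5.56 to 5.66 in wild type and 5.79 to 5.81 in knockout-labelled arrays. More unspliced or nuclear RNA could also raise primary microRNA transcripts. The 132 microRNA genes at least as bright as the median low-identifier probe set had a median difference of 0.0296 (SE 0.0571). Among them 13 were higher and 2 lower, and whether their probe sets read primary transcripts is not given, so they do not decide it. More unspliced RNA, also as a rise confined to introns of other genes, stays open, because what the low-identifier probe sets read is not given in the sources used here. The genotype, which was not tested apart from the preparation of the RNA, stays open too.

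The B cell and dendritic cell markers that rose may come from other cells left after purification or from the CD8 T cells themselves. Of 10 monocyte, macrophage and neutrophil markers above the background guide, 6 were positive and the median difference was 0.0572 (SE 0.128 over markers). A shared rise of those markers was thus not seen. More B cells and more dendritic cells cannot be told apart from a change within the T cells, because the markers of each list moved apart. The 6 B cell markers above background had a median of 0.533 (SE 0.340), with 5 positive and Ighm, by far the brightest, lower. Of 13 immunoglobulin kappa variable genes 7 were lower and 0 higher (median -0.85). Plasma cells make immunoglobulin too, so these genes do not measure the number of B cells and decide nothing here. The 7 dendritic cell markers above background had a median of 0.736 (SE 0.319), 4 of them positive, with H2-Eb1 at -0.05 beside H2-Aa at 1.21, and activated T cells are known to express Itgax. That median is the value of Bst1, whose specificity for dendritic cells was not tested.

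The fall of the Kcnma1 probe set could come from fewer naive cells among the CD8 T cells, but the largest fall in the naive list, Dapl1 at -2.39, was smaller than the Kcnma1 fall of -6.25 by far more than their standard errors, which argued against that as the whole source. Whether the whole Kcnma1 transcript changed cannot be told apart from a change at the used probe set, because the other probe set read 2.77 in wild type arrays, below the background guide of 3.83, and so decides nothing. Of 9 measured neighbours of Kcnma1 within 1 Mb, 0 passed in either direction. A sequence difference between the mice at this probe set and the genotype itself stay open and were not tested.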

How the results depend on the processing

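The 20 genes named for the largest changes kept their direction and passed under each of the 14 planned settings tallied per gene (280 values), which leave out the fit of all probe sets. Under the covariate described next all 20 kept their sign and 2 passed. Over all named genes, Dot1l included, 1447 of 1550 such values kept direction and side of the threshold, 73 lost and 17 gained a call, and 13 reversed. For lists the numbers were 361 of 406, 24, 6 and 15. The gene count moved most with the covariate added after seeing the data (the array median of the unnamed low-identifier probe sets), which left 5 genes, 3 higher and 2 lower, and 7 lists. It lies close to the genotype, so standard errors grew 2.64-fold at the median, while 1163 of the 1220 genes kept their sign and 2903 genes had an unadjusted p under 0.05. An adjusted p under 0.1 gave 1781 genes, 462 of them lower, and adding a log2 difference of at least 1 gave 289 genes, 255 higher and 34 lower, by construction. Another quantile normalization gave 625 higher and 470 lower genes, and the cause was not tested. Leaving out each array gave 615 to 1307 genes, 494 to 929 higher and 121 to 378 lower, and 8 to 11 lists. Camera with an estimated correlation passed 0 lists. The estimate was -0.00024 for the cell cycle list and -0.020 for the naive list, both below the preset 0.01. Their unadjusted camera p still rose, from 1.9e-07 to 0.0043 and from 0.00053 to 0.020. A correlation above the preset thus did not raise these p-values. In simulated data without correlation between genes, a cell cycle list shifted by 0.5 had a camera adjusted p of 3.6e-34. With an estimated correlation camera gave that list 0.0037. The estimated form therefore gave a larger p-value even where genes did not correlate. The other lists that had passed had estimates of 0.12 to 0.52, and the cause of their loss was not tested. The replicate block gave 912 genes, 874 of them shared with the 1220, and 10 lists. Among named genes Mcm6 (adjusted p = 0.117), Ldha (0.0841), Tigit (0.0576) and Zfp36 (0.0572) did not pass with it, and H2-Ab1 (0.0238) and Car1 (0.0492) did. Deviations of same-numbered arrays correlated at -0.07, -0.16 and -0.07, and 0 of 3 knockout-labelled arrays correlated best with their own number, so the paired fit rests on a shared number only.

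Reversals were limited to differences that did not pass. Dot1l ranged from -0.020 to 0.23 over the fits without 1 array, Tnfrsf17 from -0.10 to 0.22, Derl3 from -0.23 to 0.10, Mzb1 from -0.081 to 0.15 and Vcam1 from -0.0034 to 0.33. Of the 38 named genes besides Dot1l that did not pass, these 4 turned and 13 others moved by over 1.5 times when some array was left out. For example, Jchain ranged from -1.14 to -0.41, Slc4a1 from -0.63 to -0.11 and Kmt2a from 0.06 to 0.33. After quantile normalization Mzb1 was -0.10 and Vcam1 -0.0015, and after median centring Mzb1 was -0.030. The monocyte, macrophage and neutrophil list turned in 3 of the 6 fits without 1 array and the CD4 list in 2, and over all 6 the adjusted p was 0.759 to 0.976 and 0.759 to 0.962. Directions also turned at these adjusted p: monocyte, macrophage and neutrophil list, 0.807 with fry, 0.825 with the 50th percentile filter and 0.935 with median centring; CD4 list, 0.266, 0.983 and 0.947 in the same order; gamma delta list, 0.464 with fry and 0.951 with the 25th percentile filter; inhibitory list, 0.964 with fry; platelet list, 0.940 with the 50th percentile filter. Causes of the reversals were not tested. Dim signal over background limits the values of markers near 3.83 or below.

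All 10 splits of the 6 arrays into 3 and 3 were fitted. The real split gave 1220 genes and the highest other 0; it gave 10 lists and the highest other 8. In each count 1 of the 10 splits, the real one, gave a value as large, and 10 splits are too few for a share under 0.05. Every other split mixes the groups, so a difference between them widens its spread and lowers its gene count. The other splits are therefore not groupings free of that difference.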

Other observations

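Gene families and genes in this part were chosen after their values were seen. Families of at least 8 genes sharing a symbol stem were tested with camera as described for the lists, and 5 of 336 passed, of which 0 did so with an estimated correlation (adjusted p = 0.92 for each of the 5, unadjusted p under 0.05 for 3 of them). The medians of these 5 families kept their sign after quantile normalization and median centring, and the Irf median moved most in proportion, to 0.24 after quantile normalization. Of 10 guanylate-binding protein genes (Gbp), which interferon induces, 6 rose and 0 fell, with a median log2 difference of 0.71 (adjusted p = 9.4e-05). Among them were Gbp10 (0.98), Gbp3 (0.88), Gbp5 (0.74) and Gbp7 (0.69). Of 14 Ifi genes 4 rose and 0 fell (median 0.57, adjusted p = 0.00598), with Ifi202b at 1.74, of 10 Irf genes 3 rose and 0 fell (0.37, 0.000104), and of 10 Mcm replication genes 2 rose and 0 fell (0.25, 0.0219). Of 8 Schlafen genes 3 rose and 0 fell, among them Slfn5 (2.08) and Slfn3 (1.16), but the family did not pass (median 0.22, adjusted p = 0.252). In contrast, 7 of 13 immunoglobulin kappa variable genes fell and 0 rose (median -0.85, adjusted p = 7.57e-05), with Igkv4-70 at -2.64, and the heavy chain gene Ighg3 fell by 2.83 (SE 0.63).

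Ahr, a ligand-activated transcription factor, rose 4.70-fold from 6.28 ± 0.17 to 8.51 ± 0.08 (log2 difference 2.23, SE 0.12, limma adjusted p = 2.02e-05), and Bhlhe40, a transcriptional repressor, rose 3.85-fold from 8.39 ± 0.06 to 10.33 ± 0.18 (1.95, SE 0.12). Of 11 annexin genes 3 rose, among them Anxa1 (2.06, SE 0.18) and Anxa2 (2.04, SE 0.15), and Anxa5 fell (-0.67, SE 0.12), and the family did not pass (median 0.09, adjusted p = 0.352). Of 9 Tnfsf genes, ligands of the tumour necrosis factor family, 4 rose and 0 fell, among them Tnfsf11 (1.77, SE 0.11), Tnfsf4 (1.36, SE 0.18) and Tnfsf10 (1.13, SE 0.12), with a family median of -0.03 and an adjusted p of 0.124, which did not pass. Within 1 Mb of Dot1l, 1 of 111 measured genes was higher and 1 lower.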
